A study of Mus musculus with 9 samples.

How the data were processed

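Bone marrow from pelvis, tibia and femur of mice with a heterozygous Zbtb46-GFP reporter was sorted by flow cytometry into Zbtb46-neg CDPs, Zbtb46-pos CDPs and pre-CD8 DCs, and 3 arrays per population were hybridized. RNA was labelled from picogram to nanogram amounts with a pico-scale whole-transcript kit and measured on mouse whole-transcript gene arrays (Affymetrix). The labels give no sort gates and do not say whether replicates were separate mice, pools or days, so each p measures only the spread between these arrays.

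Per the submitters' processing notes, the arrays were summarized with RMA in Affymetrix Expression Console, whose versions and settings are not stated. The deposited values are an RMA signal intensity for each probe set, and they proved to be on a linear scale (7.45 to 20455.6), although log2 values had been assumed. Log2 was therefore taken, as laid down for that case, and no other scaling was applied. The table held 28853 probe sets in 9 arrays, none of them duplicates of each other. The probe table named 23410 of these, 21789 with 1 gene symbol and 1621 with several, and 5443 were not in it. Probe sets with exactly 1 symbol were kept, and for the 999 genes with several the one with the highest mean signal, which gave 19938 genes. No filter on dim genes was applied. Array medians ran from 110.2 to 118.0, and the number of arrays limits the precision. The median residual SD of a gene was 0.136 on the log2 scale.

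Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 to all 9 arrays with group means only. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 over all genes, for each of the 3 pairwise comparisons and for the moderated F test. Unadjusted p under 0.05 was reached by 5815, 3798 and 4852 genes in the comparisons of the first step, the second step and the whole span. The 3 arrays of one group lay all above or all below those of the other in 29.3%, 22.9% and 33.7% of genes, where chance gives 10%. Gene lists, 22 in all with 364 of 395 memberships measured, were tested with camera at a preset correlation of 0.01, adjusted over the lists within each comparison, and again with a correlation estimated from the data. The overlap of the steps was set against independent lists and against 100 simulated draws of unchanged groups. The position of each array was its projection on the difference of the end group means, an array being left out of its own mean.

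The lists, tests, alternatives and the rule for named genes were chosen before the data were examined. Exceptions are those said to be added later or to concern patterns already seen. The rule takes the 12 genes with the largest rise and the 12 with the largest fall at each step (6 over the whole span), among called genes whose arrays do not overlap, leaving out predicted, clone-named and small RNA genes, pseudogenes and antigen receptor segments. It adds up to 4 called members of each list with the largest change, and 16 genes whatever their values. Genes named outside it are said to be so: Xist, Eif2s3y, Ngp, S100a8, Lcn2, Camp and Fos describe arrays that stand apart and were chosen after their values were seen.

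Residuals of same-numbered arrays were checked for pairing. They correlated by 0.51, 0.42 and 0.36 between the CDP groups, by -0.01, -0.03 and 0.03 between Zbtb46-neg CDPs and pre-CD8 DCs, and by 0.11, 0.07 and 0.17 between Zbtb46-pos CDPs and pre-CD8 DCs. Differently numbered arrays of the CDP groups correlated by -0.51 to 0.38. The 0.38 was that of Zbtb46-neg replicate 3 with Zbtb46-pos replicate 2. No block was used in the main model, and a block was tried as an alternative. The other alternatives were 2 filters on dim genes, the mean of probe sets, every probe set on its own, quantile and median scaling, an intensity trend with robust moderation, array weights, fits of 2 groups, stricter thresholds, each array left out in turn, other genes for the axis, fry in place of camera, and, added after seeing the data, the 2 arrays low in Xist left out or taken as a covariate. The tally of the step at which genes were called was repeated under 2 of these settings after seeing the data.

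The steps were tested on simulated data with the same design. In each comparison 67, 67 and 66 of 19938 genes were changed by 0.5, 1 and 2. That is a smaller share than was called in the data. The adjusted p depends on this share, so the rates below need not hold for the data. At a log2 change of 0.5 from 46.3% to 47.8% of changed genes were recovered, at 1 from 89.6% to 97.0% and at 2 all (100%). False calls were 6.5%, 4.1% and 2.4% of calls, a simulated position of 0.4 was recovered as 0.407, the raised list was called, and 0 of 63 tests of unchanged lists were. The simulated noise was independent between genes and arrays. It therefore does not show how often lists are falsely called where genes or arrays vary together. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No array was left out of the main comparisons.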

Results

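Transcript levels were measured on 9 microarrays of dendritic cell (DC) progenitors sorted from the bone marrow of mice heterozygous for a Zbtb46-GFP reporter, which marks cells that transcribe the classical DC factor Zbtb46. The arrays fell into 3 groups of 3: reporter-negative common DC progenitors (Zbtb46-neg CDPs), reporter-positive common DC progenitors (Zbtb46-pos CDPs) and precursors of CD8 DCs (pre-CD8 DCs), the lineage now called cDC1. The median probe set signal per array ran from 110.2 to 118.0, and 19938 genes with a probe set of their own were compared. The number of arrays limits the precision of each value. A log2 signal near or below the table median of 6.82 was not shown to lie above background, so a difference from or to such a level may understate the change in transcript. Where such a rise is given as at least a value, this limit is meant and not the spread between arrays. The limit holds for dim genes given without these words too. The series asks for the expression signatures of these progenitors and their sequence in development, so the comparisons below follow the order Zbtb46-neg CDP, Zbtb46-pos CDP, pre-CD8 DC.

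The first comparison asks what separates reporter-positive from reporter-negative cells within the CDP gate. Zbtb46-pos CDPs had more transcript of Id2, the inhibitor of E proteins that cDC1 development needs, at 10.42 ± 0.07 against 6.56 ± 0.40 (log2 signal, mean ± SD, n = 3), a rise of at least 3.86 given the dim starting level. Batf3, a cDC1 transcription factor, rose 3.50-fold, from 7.97 ± 0.23 to 9.77 ± 0.24. The MHC class II chain gene H2-Aa rose by at least 4.98, from 6.11 ± 0.75 to 11.09 ± 0.67. Erg, a stem cell factor, fell by 2.06 and the neutrophil protease gene Ctsg fell by 2.59 on the log2 scale. Ribosome biogenesis genes were lower almost throughout, with 20 of 22 lower and none higher.

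Of the 19938 genes, 768 were higher and 2105 lower in Zbtb46-pos CDPs (limma, adjusted p under 0.05). Among named genes, the largest rises after H2-Aa were in the interferon-inducible gene Ifi205 (log2 difference 4.93, SE 0.169), the phospholipase-like gene Plbd1 (4.92, SE 0.344), Serpinb10 (4.25, SE 0.183) and Samd9l (4.23, SE 0.219). Cd74, the MHC class II invariant chain, rose by 4.07 with an SE of 0.495, since the arrays of the Zbtb46-pos CDPs ranged from 9.44 to 11.58. Slamf7 (3.92), Cd226 (3.30), Slc46a3 (3.12), the adhesion molecule gene L1cam (3.01) and Cd7 (2.96) completed the genes with the largest rises together with Id2. The largest falls were in Cd69, the early activation marker (-3.0, SE 0.103), the glutathione transferase Mgst1 (-2.83), the peroxisomal transporter Abcd2 (-2.76), Adgrl4 (-2.58) and Ctsg. Dntt, the lymphoid DNA polymerase, fell by 2.49, the histone gene H2bc4 fell by 2.43, and Il12a, which encodes an interleukin 12 subunit, fell by 2.17. Drc7, Erg, the basophil protease gene Mcpt8 and the interferon-inducible GTPase Gbp3 fell by 2.14, 2.06, 2.04 and 2.02.

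The cDC1 lineage list had 13 members higher and 0 lower of 22 measured, 14 and 1 when adjusted over the list alone (camera adjusted p = 9.31e-11). Besides Id2, Batf3 and Ifi205, its members Naaa, a lysosomal amidase, and Tlr3, a receptor for double-stranded RNA, rose by 2.06 and 2.04. Xcr1, the chemokine receptor of mature cDC1, rose by 0.56 from a low 5.84 ± 0.25, and the surface marker Cd24a rose by 0.74. The lectin receptor Clec9a, at 9.10 ± 0.55 and 9.41 ± 0.06, and Irf8, the lineage regulator, at 12.52 ± 0.15 and 12.97 ± 0.32, did not pass the test (adjusted p = 0.375 and 0.078). Nor did Nfil3 (adjusted p = 0.48), Cd8a (0.525) or Kit (0.316). Of the MHC class II list, 6 of 9 measured members were higher and 0 lower, 7 and 0 when adjusted over the list alone (camera adjusted p = 4.05e-06). That list's adjusted p = 0.31 with an estimated correlation. H2-Ab1 and H2-Eb1 rose by 2.88 and 1.65. Zbtb46 itself rose by 0.71 (SE 0.175, adjusted p = 0.0261), from 6.53 ± 0.34 to 7.24 ± 0.23. The CDP groups were sorted on the reporter of this gene, so its difference checks the sort and is not a separate result.

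The list of DC transcription factors and E/Id proteins had 9 members higher and 2 lower of 32, 12 and 4 when adjusted over the list alone (camera adjusted p = 0.036, and adjusted p = 0.753 with an estimated correlation). Bcl6, a repressor in DC development, rose by 1.67 beside Id2 and Batf3, while Zeb2, a repressor that favours other myeloid fates, fell by 1.83. Of the cDC2 lineage list, 5 of 15 members were higher and 4 lower, 6 and 5 when adjusted over the list alone, without a call for the list (camera adjusted p = 0.701). Its members Cd209a (2.54) and S100a4 (1.40) rose, while Sirpa, a cDC2 surface marker, fell by 0.56. Flt3, the receptor for the main DC growth factor, fell by 0.49, and Csf1r, the macrophage colony-stimulating factor receptor gene, fell by 0.91. The integrin gene Itgax, which encodes CD11c, rose by 0.85.

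Among stem and progenitor genes, 14 of 21 were lower and 1 higher, with the same 14 and 1 when adjusted over the list alone (camera adjusted p = 1.54e-08, and adjusted p = 0.31 with an estimated correlation). Cdk6, a cell cycle kinase of progenitors, fell by 1.61 and Myc fell by 1.60. The ribosome biogenesis list had 0 members higher and 20 lower of 22, 0 and 22 when adjusted over the list alone (camera adjusted p = 2.69e-16). Gnl3, Srm, Polr1b and Dkc1, which act in nucleolar or polyamine metabolism, fell by 1.60, 1.49, 1.30 and 1.25. Oxidative phosphorylation genes fell as a group, 9 of 12 lower and 0 higher, 10 and 0 when adjusted over the list alone (camera adjusted p = 2.94e-06). With an estimated correlation that list had adjusted p = 0.31. Sdhb, a subunit of respiratory complex II, fell by 0.58 and Atp5a1, an ATP synthase subunit, fell by 0.59. The mitosis list moved the other way, with 6 of 19 higher and 0 lower, 9 and 0 when adjusted over the list alone (camera adjusted p = 0.000135, and adjusted p = 0.31 with an estimated correlation). Nusap1 (0.73), Mki67 (0.63) and Birc5 (0.55) were among the members that rose. In the DNA replication list, 2 of 20 members were higher and 8 lower, the same when adjusted over the list alone (camera adjusted p = 0.0467, and adjusted p = 0.395 with an estimated correlation). The helicase subunits Mcm7 and Mcm6 both fell by 0.61, whereas Ccne1, the cyclin of S phase entry, rose by 0.79.

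The granulocyte list had 0 members higher and 4 lower of 15, the same when adjusted over the list alone, and was called lower (camera adjusted p = 0.0384, and adjusted p = 0.753 with an estimated correlation). The call was lost with the replicate number as a block (adjusted p = 0.0555), with the 30% dimmest genes dropped (adjusted p = 0.177) and with the arrays low in Xist as a covariate (adjusted p = 0.126). Its mean was -0.43 and its median 0.14, so the signs differed; without the 2 arrays low in Xist the median was -0.54, with 6 members lower (camera adjusted p = 0.000386). The primary granule genes Ctsg, Mpo (-1.72) and Prtn3 (-1.20) and Csf3r (-0.91), the granulocyte colony-stimulating factor receptor gene, fell, while Elane, also of the primary granules, did not pass the test (-1.62, adjusted p = 0.134). Secondary granule transcripts did not pass the test and stood apart in replicate 1 of both CDP groups: Ngp exceeded the other arrays of its group by 4.21 in the Zbtb46-neg and 6.80 in the Zbtb46-pos CDPs. Of the monocyte and macrophage list, 4 of 15 were higher and 5 lower, with the same counts when adjusted over the list alone (camera adjusted p = 0.939), where the median (0.05) and mean (0.06) were opposite in sign to the test. Fn1, Klf4 and Irf5 rose by 1.45, 1.35 and 1.01, and the coagulation factor gene F13a1 fell by 1.87. The B cell list had 0 higher and 4 lower of 13, the same when adjusted over the list alone (camera adjusted p = 0.104). Its members Dntt, Blnk (-0.99) and Il7r (-0.96), all used in early lymphoid cells, were among those that fell. The pDC list had 2 of 14 higher and 3 lower, 3 and 4 when adjusted over the list alone (camera adjusted p = 0.701). Smim5 rose by 1.07 and the RNA sensor Tlr7 fell by 1.19.

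The other lists gave no call with camera at this step. The type I interferon list had 4 of 16 higher and 2 lower (adjusted p = 0.701, median -0.05, mean 0.08), with the regulator Irf7 (1.24) and Mx1 (0.82) up and Ifit2 (-0.78) and the RNA sensor Ifih1 (-0.75) down. The Toll-like receptor pathway had 3 of 13 higher and 2 lower (adjusted p = 0.709, median -0.08, mean 0.19), and Tlr12 rose by 1.42. MHC class I processing had 1 of 12 higher and 3 lower (adjusted p = 0.25), Erap1 and Calr falling by 0.57 and 0.55. DC maturation had 2 of 13 higher and 1 lower (adjusted p = 0.0963), the costimulatory gene Cd86 rising by 1.58. Lysosomal genes had 3 of 16 higher and 5 lower (adjusted p = 0.205), the protease gene Ctsd falling by 1.06. Cytokine and chemokine receptors had 4 of 21 higher and 5 lower (adjusted p = 0.939, median 0.06, mean 0.05, test lower), Cxcr3 rising by 0.99. Of the immediate early list 1 of 16 was higher (adjusted p = 0.581), Klf6 with 0.92. The erythroid, megakaryocyte, mast cell and basophil list had 1 of 14 higher and 1 lower (adjusted p = 0.701, median 0.06, mean -0.04), Car1 (0.61) and Mcpt8. The T, NK and innate lymphoid list also had 1 of 14 higher and 1 lower (adjusted p = 0.247), Thy1 (0.90) and Il7r. When adjusted over the list alone, these lists had in the same order 4 and 2, 4 and 4, 2 and 4, 2 and 1, 4 and 7, 6 and 5, 0 and 0, 1 and 1, and 1 and 1 members higher and lower.

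Without the 2 arrays that were low in Xist, which are described after the comparisons, 1737 genes were higher and 2758 lower, and the rise of Zbtb46 (0.45, adjusted p = 0.0891), the calls of Cd200, Cd274, Sdha and Tapbp, and the calls of the DC transcription factor and DNA replication lists (both adjusted p = 0.133) were lost, while Irf8 passed (0.35, adjusted p = 0.00866). The immediate early list then had 2 members higher and 6 lower and a median of -0.12 in place of 0.13, still without a call (adjusted p = 0.599). After another quantile normalization of the arrays 1216 genes were higher and 1572 lower, and the DNA replication list was not called (adjusted p = 0.475), nor with the 30% dimmest genes dropped (adjusted p = 0.234). With fry the DC transcription factor list was not called (adjusted p = 0.111). The MHC class I processing and B cell lists, not called with camera, were called lower with fry (adjusted p = 0.0128 and 0.0206). The DC maturation list gained a call as higher with fry (adjusted p = 0.0307). With camera it did so with the 30% dimmest genes dropped (0.0282), the mean of probe sets (0.0406) and the arrays low in Xist as a covariate (0.0434). It stayed uncalled with those arrays left out (0.146) and with an estimated correlation (0.398).

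**Figure D1:**
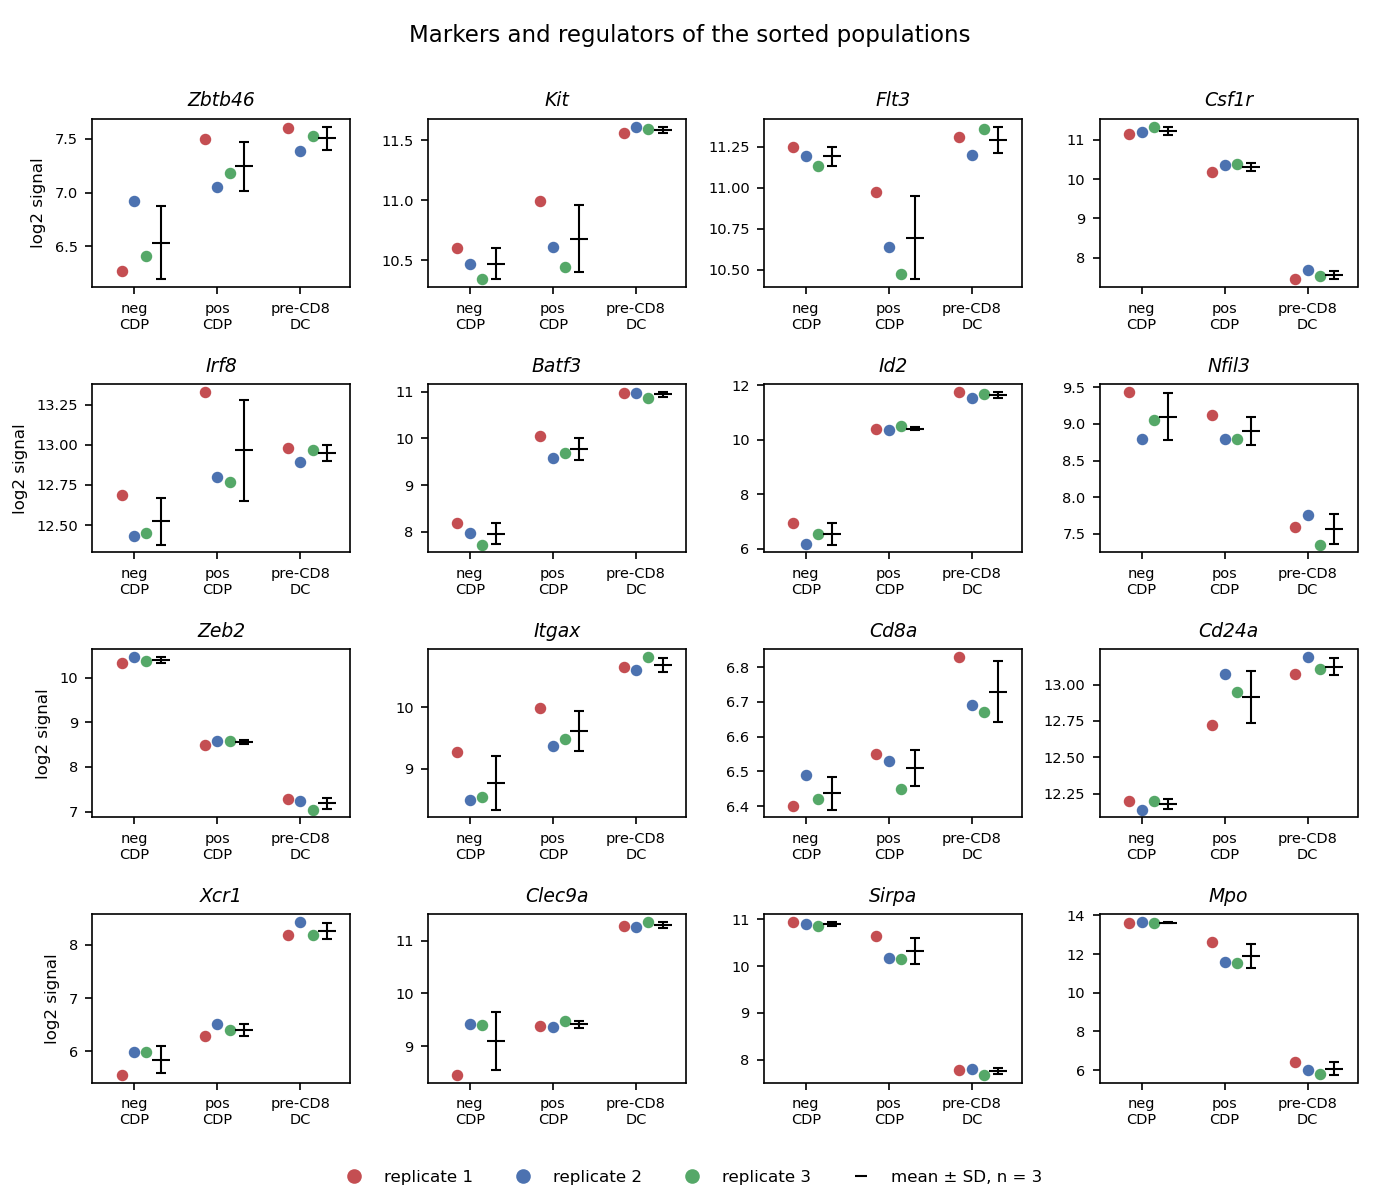
Signal of 16 genes fixed as markers and regulators of the sorted populations, as log2 signal (vertical axes, which differ between panels and do not start at 0) in Zbtb46-neg CDPs, Zbtb46-pos CDPs and pre-CD8 DCs; points are arrays coloured by replicate number, bars mean ± SD of 3 arrays. Id2 rose from 6.56 over 10.42 to 11.65 and Zeb2 fell from 10.39 over 8.56 to 7.18, while Clec9a, with 9.10, 9.41 and 11.29, passed the test at the second step and not at the first.

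The second comparison asks what changes between Zbtb46-pos CDPs and pre-CD8 DCs. Clec9a rose 3.68-fold in pre-CD8 DCs, from 9.41 ± 0.06 to 11.29 ± 0.05 (log2 signal, n = 3), and Xcr1 rose by at least 1.86, from 6.41 ± 0.11 to 8.26 ± 0.14. Tlr3 rose 11.6-fold, from 7.95 ± 0.23 to 11.49 ± 0.02, and Ciita, the master regulator of MHC class II genes, rose 6.89-fold. Csf1r fell from 10.31 ± 0.10 to 7.56 ± 0.11, Sirpa from 10.33 ± 0.28 to 7.75 ± 0.07 and Mpo, the neutrophil peroxidase, from 11.91 ± 0.62 to 6.08 ± 0.32. DNA replication genes fell together, 16 of 20 lower and none higher.

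At this step 949 genes were higher and 370 lower in pre-CD8 DCs (limma, adjusted p under 0.05). The largest rises were in the MHC class II gene H2-Eb1 (3.75, SE 0.261), Gpr141b (3.68, SE 0.110), Tlr3 (3.54), Phf11a (3.43), the adaptor gene Scimp (3.12), Snx22 (3.01), Slfn5 (2.99) and Cd74 (2.96). Clec4b1, H2-Ab1, Ciita and Slamf8 followed with 2.88, 2.87, 2.79 and 2.75. The largest falls were in Mpo (-5.83, SE 0.275), Prtn3 (-4.11), the glutamate receptor gene Gria3 (-3.53), Ctsg (-3.05), the neutrophil elastase gene Elane (-2.92, SE 0.645) and Cd93, a surface protein of progenitors (-2.90). F13a1 fell by 2.90, the fibronectin gene Fn1 fell by 2.79, and Csf1r, Igfbp4, Sirpa and Upk1b fell by 2.74, 2.70, 2.58 and 2.53.

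The cDC1 lineage list had 16 members higher and 1 lower of 22, 17 and 1 when adjusted over the list alone (camera adjusted p = 7.44e-22). Snx22, Gcsam and Septin3 rose by 3.01, 2.46 and 2.43, Id2 by 1.23 and Batf3 by 1.17. The member that fell was Nfil3, a transcription factor that acts early in cDC1 development (-1.33, SE 0.173). Irf8 stayed at a high level in both groups, 12.97 ± 0.32 and 12.94 ± 0.05, without passing the test (adjusted p = 0.948). Cd24a (0.21, adjusted p = 0.264), Cd8a (0.22, adjusted p = 0.12) and Zbtb46 (0.27, adjusted p = 0.463) did not pass either. MHC class II genes had 7 of 9 members higher and 0 lower, 9 and 0 when adjusted over the list alone (camera adjusted p = 2.02e-12, and adjusted p = 0.0524 with an estimated correlation). MHC class I processing genes rose as a group, 4 of 12 higher and 0 lower, 6 and 0 when adjusted over the list alone (camera adjusted p = 2.51e-05). The peptide transporter gene Tap2 and the immunoproteasome genes Psmb9, Psmb10 and Psmb8 rose by 0.76, 0.71, 0.70 and 0.69.

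The Toll-like receptor pathway had 6 of 13 members higher and 0 lower, 7 and 0 when adjusted over the list alone (camera adjusted p = 4.49e-08, and adjusted p = 0.089 with an estimated correlation). Tlr13, Tlr1 and Tlr2 rose by 1.76, 1.47 and 0.83 beside Tlr3. Of the type I interferon list 6 of 16 were higher and 0 lower, 8 and 0 when adjusted over the list alone (camera adjusted p = 1.46e-05). Irf7, Usp18, Ifih1 and Stat2 rose by 1.95, 1.12, 1.08 and 0.81. The immediate early list was called higher (camera adjusted p = 0.022, and adjusted p = 0.636 with an estimated correlation) with 1 of 16 members higher and 0 lower, 2 and 0 when adjusted over the list alone. That member was the orphan nuclear receptor gene Nr4a1 (0.68). With the 2 arrays low in Xist left out, 12 members were higher and 0 lower, and the median was 0.59 in place of 0.27 (camera adjusted p = 3.01e-08). Immediate early transcripts stood apart in replicate 1 of the CDPs: Fos exceeded the other arrays of its group by 0.79 in the Zbtb46-neg and 1.39 in the Zbtb46-pos CDPs. The growth factor receptors Flt3 and Kit rose by 0.59 and 0.90, and Itgax rose by 1.07.

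The cDC2 lineage list was called lower (camera adjusted p = 0.00151, and adjusted p = 0.104 with an estimated correlation), although 10 of its 15 members were not called. There were 1 higher and 4 lower, 2 and 6 when adjusted over the list alone, and the median was -0.19. Sirpa, the lectin gene Clec10a (-1.43), Zeb2 (-1.38) and the fractalkine receptor gene Cx3cr1 (-1.06) were the members that fell. The granulocyte list had 0 of 15 higher and 5 lower, 0 and 6 when adjusted over the list alone (camera adjusted p = 9.23e-08, and adjusted p = 0.261 with an estimated correlation). Its primary granule genes Mpo, Prtn3, Ctsg and Elane fell. The list median was -0.95, and -0.12 without the 2 arrays low in Xist. Elane was 11.65 in replicate 1 of the Zbtb46-pos CDPs, against 8.87 and 8.68 in the other arrays of that group. Stem and progenitor genes had 3 of 21 higher and 5 lower, 3 and 11 when adjusted over the list alone (camera adjusted p = 0.000241, and adjusted p = 0.374 with an estimated correlation). Adgrg1 (-1.75), Cd34 (-1.56) and Cdk6 (-1.27) fell. Monocyte and macrophage genes went both ways, 4 of 15 higher and 5 lower, 6 and 6 when adjusted over the list alone (camera adjusted p = 0.149), the lysozyme gene Lyz2 rising by 1.22.

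In the DNA replication list 0 of 20 members were higher and 16 lower, 0 and 19 when adjusted over the list alone (camera adjusted p = 3.89e-19). The cyclins Ccne1 and Ccne2 fell by 0.96 and 0.86 and the helicase subunits Mcm2 and Mcm6 fell by 0.88 and 0.77. No mitosis gene of 19 passed the test in either direction, nor when adjusted over the list alone (camera adjusted p = 0.671). Ribosome biogenesis genes turned upward, 3 of 22 higher and 0 lower, also when adjusted over the list alone (camera adjusted p = 3.14e-05). Gnl3, Wdr43 and Fbl rose by 0.60, 0.38 and 0.37. Oxidative phosphorylation was called higher (camera adjusted p = 0.0111, and adjusted p = 0.374 with an estimated correlation) with 1 of 12 members higher and 0 lower, 2 and 0 when adjusted over the list alone. Sdhb was that member (0.47).

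The other lists gave no call. DC transcription factors and E/Id proteins had 3 of 32 higher and 2 lower (camera adjusted p = 0.436, median -0.02, mean 0.07). DC maturation had 2 of 13 higher and 0 lower (adjusted p = 0.286), with Cd86 (1.72) and Cd200 (0.67). The pDC list had 2 of 14 higher and 1 lower (adjusted p = 0.46, median -0.04, mean 0.16), Ccr9 rising by 1.40 and Smim5 falling by 0.60. Cytokine and chemokine receptors had 7 of 21 higher and 4 lower (adjusted p = 0.46, median -0.07, mean 0.13), with Cxcr3 (2.59) and the interferon gamma receptor gene Ifngr1 (1.45) up. Lysosomal genes had 1 of 16 higher and 3 lower (adjusted p = 0.256), Npc2 rising by 0.50 and Ctsd falling by 1.19. The B cell, T and NK cell, and erythroid lists had 0 members past the test (adjusted p = 0.46, 0.149 and 0.46). When adjusted over the list alone, these lists had in the same order 5 and 2, 2 and 0, 2 and 2, 8 and 7, 2 and 4, 0 and 0, 0 and 0, and 0 and 0 members higher and lower.

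Without the 2 arrays low in Xist, 2496 genes were higher and 1570 lower, the DC transcription factor list was called higher (adjusted p = 0.00761) and the oxidative phosphorylation list was not called (adjusted p = 0.0759). After another quantile normalization 749 genes were higher and 654 lower, and the oxidative phosphorylation list was not called (adjusted p = 0.914). That list and the immediate early list also lost their calls with the 30% dimmest genes dropped (both adjusted p = 0.0761) and with fry (adjusted p = 0.065 and 0.385). The monocyte and macrophage list, not called with camera, was called lower with fry (adjusted p = 1.31e-05).

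**Figure D2:**
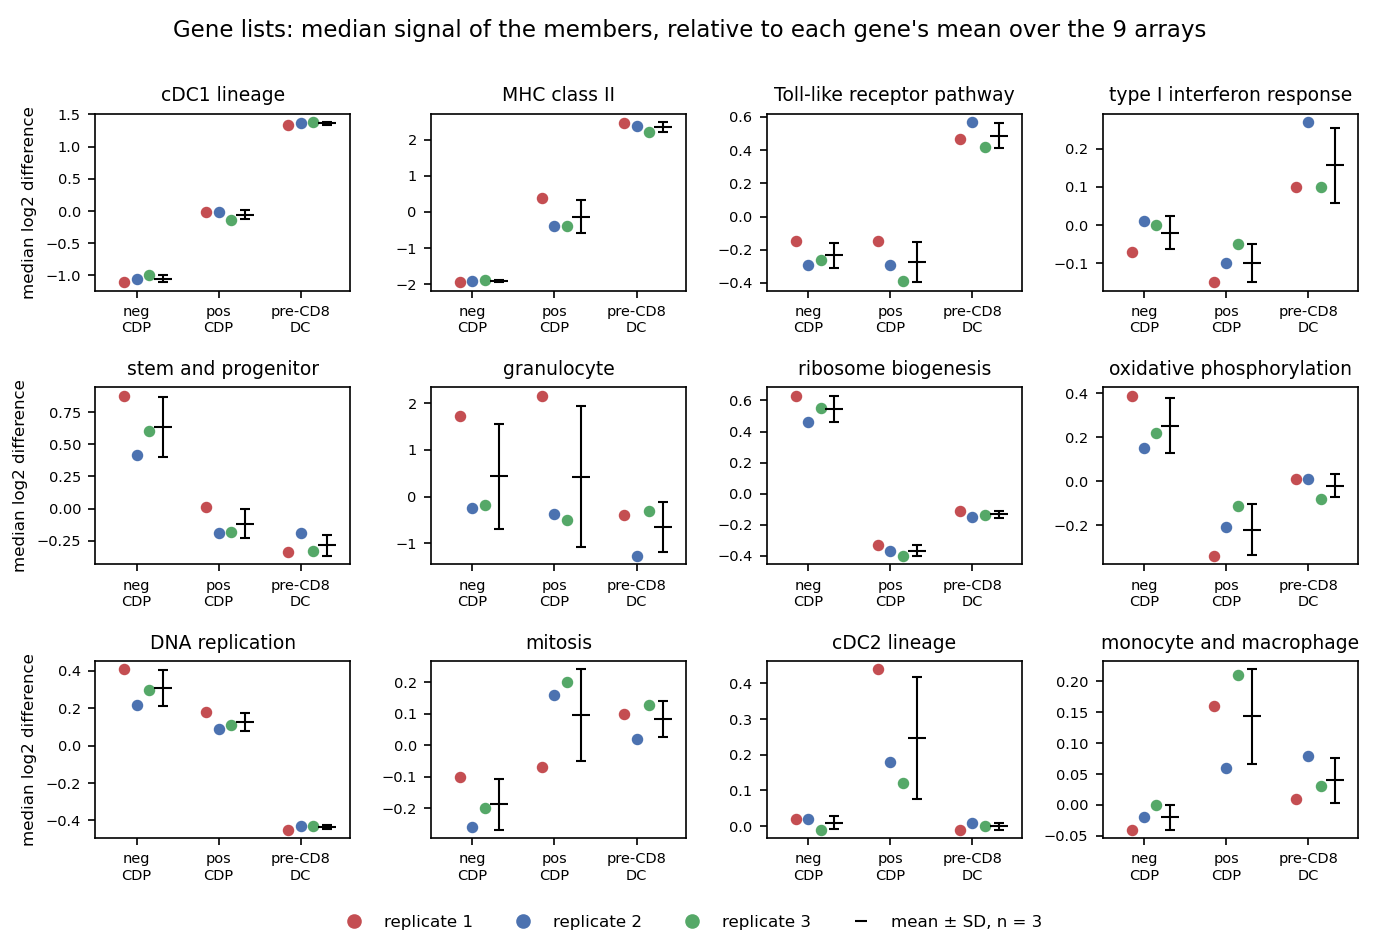
Median log2 signal of the measured members of 12 gene lists, each gene taken relative to its mean over the 9 arrays (vertical axes, which differ between panels), for the 3 populations; points are arrays coloured by replicate number, bars mean ± SD of 3 arrays. The cDC1 list lay at -1.11 to -0.99 in Zbtb46-neg CDPs, -0.14 to -0.01 in Zbtb46-pos CDPs and 1.34 to 1.38 in pre-CD8 DCs, and the granulocyte list was highest in replicate 1 of both CDP groups (1.72 and 2.16).

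The third comparison covers the whole span, from Zbtb46-neg CDPs to pre-CD8 DCs. H2-Aa rose by at least 7.50, from 6.11 ± 0.75 to 13.61 ± 0.06 (log2 signal, n = 3), and Cd74 rose by at least 7.03, from 6.12 ± 0.42 to 13.15 ± 0.03. Mpo went the other way, from 13.63 ± 0.04 to 6.08 ± 0.32, where it fell by 7.54 or more. Slamf7 rose by at least 5.79, from 5.48 ± 0.07 to 11.28 ± 0.02, and Zbtb46 rose by 0.98 (SE 0.175, adjusted p = 0.00454). The rise of Zbtb46 starts from cells sorted as negative for its reporter, so the sort may set part of it. There were 1282 genes higher and 1841 lower in pre-CD8 DCs (limma, adjusted p under 0.05). Without the 2 arrays low in Xist they were 1875 and 2146, and the calls of the MHC class I and DC maturation lists given below were lost (adjusted p = 0.0522 and 0.0634), while Irf8 passed (0.51, adjusted p = 0.000722). With fry the calls of the DC transcription factor and immediate early lists were lost (adjusted p = 0.0882 and 0.198). The cDC2, monocyte and macrophage, and lysosome lists, not called with camera, were called lower with fry (adjusted p = 9.83e-05, 3.99e-06 and 0.0065).

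Besides these, the largest measured rises were in Plbd1 (6.50), H2-Ab1 (5.75) and Ifi205 (5.73), and the largest falls in Ctsg (-5.64), Prtn3 (-5.31), F13a1 (-4.76), Cd93 (-4.69) and Elane (-4.54). All 9 measured MHC class II genes were higher, also when adjusted over the list alone (camera adjusted p = 2.16e-14, and adjusted p = 0.0564 with an estimated correlation). The cDC1 list had 19 of 22 higher and 1 lower, 21 and 1 when adjusted over the list alone (camera adjusted p = 4.3e-27). Tlr3, Id2 and Naaa rose by 5.58, 5.10 and 4.29, Batf3 by 2.97, Xcr1 by 2.42, Clec9a by 2.19 and Cd24a by 0.95. Cd8a rose by 0.29 and stayed low at 6.73 ± 0.09, whereas Irf8 (0.42, adjusted p = 0.0968) and Flt3 (0.10, adjusted p = 0.758) did not pass the test. Nfil3 fell by 1.53. The list of DC transcription factors had 10 of 32 higher and 5 lower, 15 and 7 when adjusted over the list alone (camera adjusted p = 0.0143, and adjusted p = 0.64 with an estimated correlation), with Bcl6 (2.58) up and Zeb2 (-3.21) down. MHC class I processing had 6 of 12 higher and 1 lower, the same when adjusted over the list alone (camera adjusted p = 0.0374, and adjusted p = 0.159 with an estimated correlation), Tapbp and Tap1 rising by 0.82 and 0.66. DC maturation had 3 of 13 higher and 1 lower, the same when adjusted over the list alone (camera adjusted p = 0.0309, and adjusted p = 0.23 with an estimated correlation). Cd86, Cd200 and Relb rose by 3.29, 1.25 and 0.63, and the checkpoint ligand gene Cd274 fell by 0.43.

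The Toll-like receptor pathway had 8 of 13 higher and 2 lower, 9 and 2 when adjusted over the list alone (camera adjusted p = 8.45e-06, and adjusted p = 0.159 with an estimated correlation). Tlr13 and Tlr12 rose by 2.24 and 1.63 while Tlr7 fell by 1.42. Type I interferon genes had 5 of 16 higher and 0 lower, 5 and 1 when adjusted over the list alone (camera adjusted p = 0.0034, and adjusted p = 0.0641 with an estimated correlation), Irf7, Usp18 and Mx1 rising by 3.19, 1.80 and 1.62. The immediate early list had 6 of 16 higher and 0 lower, 6 and 1 when adjusted over the list alone (camera adjusted p = 0.0187, and adjusted p = 0.64 with an estimated correlation), with Dusp1 (1.56), Klf6 (1.33) and Junb (1.31). Leaving out the 2 arrays low in Xist gave 9 higher and 2 lower. Replicate 1 of the CDPs stood apart in Dusp1 too, by 0.60 and 1.46 above the other arrays of its group.

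Among stem and progenitor genes 1 of 21 was higher, Kit (1.12), and 14 were lower, 1 and 16 when adjusted over the list alone (camera adjusted p = 5.07e-11, and adjusted p = 0.159 with an estimated correlation). Adgrl4, Adgrg1, Cdk6 and Cd34 fell by 3.82, 3.01, 2.88 and 2.66. The granulocyte list had 0 of 15 higher and 6 lower, the same when adjusted over the list alone (camera adjusted p = 8.42e-06, and adjusted p = 0.283 with an estimated correlation). The list median was -0.50, and -0.09 without the 2 arrays low in Xist. Ngp differed between the pre-CD8 DC arrays as well, at 8.30, 5.78 and 8.54. The B cell list had 0 of 13 higher and 4 lower, 1 and 4 when adjusted over the list alone (camera adjusted p = 0.026, and adjusted p = 0.164 with an estimated correlation), with Dntt (-2.37), Blnk (-1.03) and Cd79b (-0.80). DNA replication had 0 of 20 higher and 17 lower, 0 and 19 when adjusted over the list alone (camera adjusted p = 1.14e-15), with Mcm2 (-1.41), Mcm6 (-1.39) and Mcm3 (-1.32). Mitosis had 7 of 19 higher and 0 lower, the same when adjusted over the list alone (camera adjusted p = 4.49e-05, and adjusted p = 0.164 with an estimated correlation), Nusap1 and Mki67 rising by 0.72 and 0.52. Ribosome biogenesis had 0 of 22 higher and 14 lower, 0 and 18 when adjusted over the list alone (camera adjusted p = 2.43e-11), Srm and Nolc1 falling by 1.18 and 1.02. Oxidative phosphorylation had 0 of 12 higher and 4 lower, 0 and 8 when adjusted over the list alone (camera adjusted p = 0.000772, and adjusted p = 0.232 with an estimated correlation), Sdha and Ndufv1 falling by 0.56 and 0.49.

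With camera no call was made for the remaining lists over the whole span. The cDC2 list had 5 of 15 higher and 6 lower (adjusted p = 0.494), with Cd209a (3.12) up and Sirpa (-3.14) and Clec10a (-1.90) down. The monocyte and macrophage list had 6 of 15 higher and 5 lower (adjusted p = 0.717, median 0.05, mean -0.34), Irf5 rising by 1.64 and Csf1r and Cx3cr1 falling by 3.66 and 1.39. The pDC list had 4 of 14 higher and 5 lower (adjusted p = 0.826, median -0.15, mean 0.12, test lower), Ccr9 rising by 1.84. Lysosomal genes had 4 of 16 higher and 7 lower (adjusted p = 0.112), Ctsh rising by 0.79 and Ctsd falling by 2.25. Cytokine and chemokine receptors had 8 of 21 higher and 5 lower (adjusted p = 0.505), Cxcr3 rising by 3.58 and Csf3r falling by 2.25. The T, NK and innate lymphoid list had 0 of 14 higher and 2 lower (adjusted p = 0.826, median 0.03, mean -0.14), Nkg7 and Il7r. The erythroid list had 0 of 14 higher and 1 lower (adjusted p = 0.826, median 0.07, mean -0.11), Mcpt8. When adjusted over the list alone, these lists had in the same order 5 and 6, 6 and 5, 4 and 5, 5 and 9, 8 and 6, 0 and 2, and 0 and 1 members higher and lower. Of the 66 list tests over the 3 comparisons 36 were called, and 10 were called with an estimated correlation. A wrong split of the 9 arrays, described at the end, gave as many as 30 calls at the preset correlation.

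The step at which the genes of the whole span were called was tallied, without a test. Of the 1841 lower genes, 1032 (56.1%) were called lower at the first step alone and 155 (8.4%) at the second step alone. At neither step were 498 (27.1%) called. Of the 1282 higher genes, 356 (27.8%) were called higher at the first step alone and 361 (28.2%) at the second alone. At neither step were 376 (29.3%) called. A gene not called at a step may still have changed there, and the first step had 2873 calls against 1319. The tally therefore does not show when genes changed. After another quantile normalization the first and second step held 851 (46.0%) and 309 (16.7%) of 1849 lower genes and 629 (41.0%) and 321 (20.9%) of 1534 higher genes, so the contrast between rising and falling genes depended on the scaling. Without the 2 arrays low in Xist they held 1201 and 268 of 2146 lower and 389 and 723 of 1875 higher genes. Genes that changed in the same direction at both steps numbered 345, of which 189 were higher, Id2, Batf3, Tlr3 and H2-Ab1 among them, and 156 lower, including Zeb2, Csf1r, Cdk6 and Mpo. Independent lists of those sizes would share 36.6 and 39.1 genes. That baseline treats all genes alike. With genes in 4 bins by mean signal, the brightest bin held 413 higher and 1018 lower calls of the first step, the dimmest 73 and 46. Lists that both favour bright genes share more than the baseline without a link between the steps. The excess over it therefore does not by itself show genes that keep their direction. The excess was smaller in proportion without the 2 arrays low in Xist, with 396 higher and 293 lower at both steps against 217.5 and 217.2. Simulated unchanged groups shared 0, which their lack of calls gives by construction. Others turned around: 308 genes were lower and then higher, Myc and Ifih1 among them, and 34 were higher and then lower, among them Fn1 and Ccne1, where independent lists would share 100.2 and 14.3. These counts moved with the settings: 939 and 678 without the 2 arrays low in Xist, against 345.3 and 136.8, and 168 and 117 after another quantile normalization. The steps share the Zbtb46-pos CDP arrays with opposite sign, so part of the excess in the genes that turned around may come from those arrays. Across genes, which are not independent replicates, the log2 differences of the steps had a correlation of -0.01 and a covariance of -0.0011, against -0.497 and -0.0091 in simulated unchanged groups. The share of genes with the same sign at both steps went the other way, 30.8% against 33.4% in those groups.

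On an axis from 0 for the mean of the Zbtb46-neg CDPs to 1 for that of the pre-CD8 DCs, built on the 3123 genes called between them, the Zbtb46-pos CDPs lay at 0.568 ± 0.012 (SD, n = 3). The Zbtb46-neg CDPs, each left out of its own group mean, lay at 0.012 ± 0.014 and the pre-CD8 DCs at 0.992 ± 0.003. No test was made of the position, since an exact test of 3 against 3 arrays cannot give a p below 0.1. By the moderated F test of limma 3816 genes differed between the populations.

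The arrays of replicate 1 in both CDP groups stood apart from the other 7. Xist, the transcript of the inactive X chromosome, was at 5.59 and 5.30 in them and between 11.85 and 12.29 in the others. Eif2s3y, a gene on the Y chromosome, was at 6.92 and 6.51 against 3.63 to 3.78. Neutrophil transcripts were higher in these arrays than in the others of their group, with S100a8 by 3.64 and 5.76, Lcn2 by 2.61 and 5.81 and Camp by 2.5 and 4.67 in the Zbtb46-neg and Zbtb46-pos CDPs. Within this pair of arrays the log2 differences between Zbtb46-pos and Zbtb46-neg CDPs had a correlation of 0.701 across genes with those of the other CDP arrays. Of the 4495 genes called in the other arrays, 3953 (87.9%) had the same sign within the pair. The pre-CD8 DC group held no array of this kind, so the second step and the whole span have no value within it. With the 2 arrays against the other 7 as a covariate, a choice made after seeing the data, 2026 genes were higher and 3333 lower at the first step, 2057 and 1073 at the second, and 1804 and 2052 over the whole span. Same-numbered arrays of the CDP groups deviated together (correlations 0.51, 0.42 and 0.36). Replicate 3 of the Zbtb46-neg and replicate 2 of the Zbtb46-pos CDPs did so too (0.38), so pairing by number beyond replicate 1 is not shown. With the replicate number as a block in a fit of the 2 CDP groups alone, 988 genes were higher and 2186 lower at the first step.

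**Figure D3:**
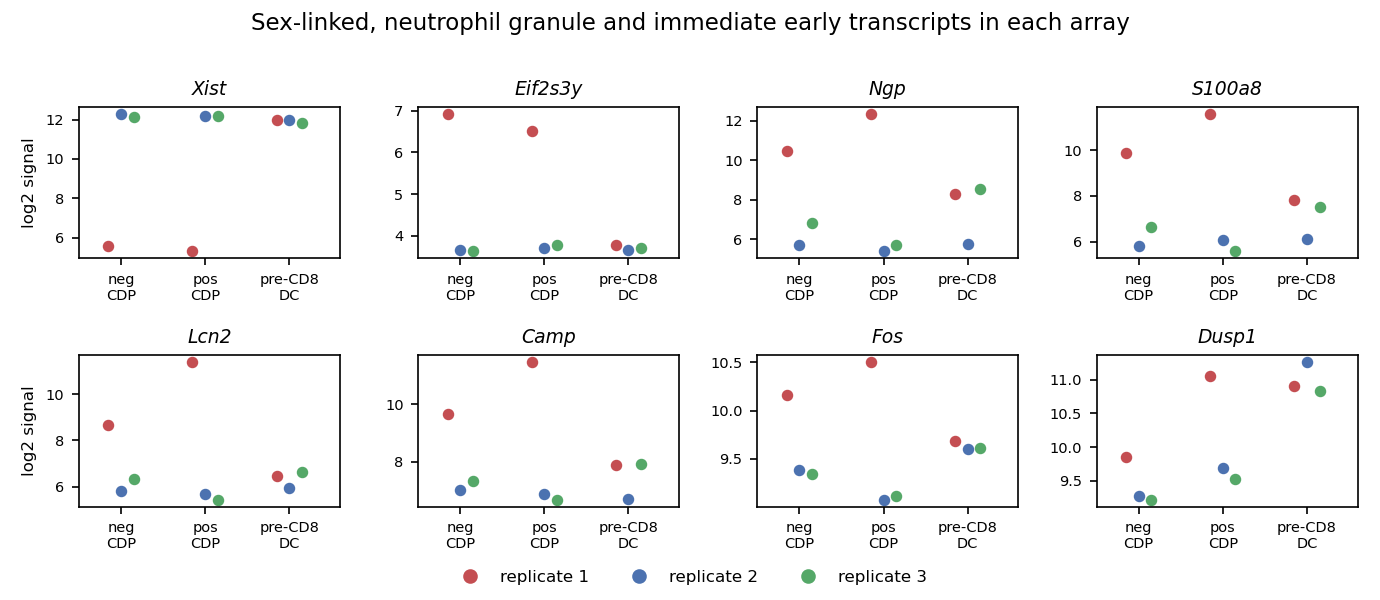
Log2 signal (vertical axes, which differ between panels and do not start at 0) of a transcript of the inactive X chromosome (Xist), a Y-linked gene (Eif2s3y), 4 neutrophil genes and 2 immediate early genes in each of the 9 arrays. Points are arrays, coloured by replicate number. Replicate 1 of the Zbtb46-neg and Zbtb46-pos CDPs was low in Xist (5.59 and 5.30) and high in Ngp (10.48 and 12.36), where the other 7 arrays lay between 5.39 and 8.54.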

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

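Both results here came from probe sets that the comparisons leave out, and their tests were added after the data were seen. Of the 5443 probe sets that the probe table does not name, 362 (6.7%) differed between the populations at an adjusted p under 0.05 of the limma F test. Of the 1621 probe sets assigned to several genes, 219 (13.5%) did, where 3766 of the 21789 probe sets of 1 gene (17.3%) passed. They drew attention as signal in data outside the main comparisons, and no explanation was tested.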

How the results depend on the processing

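The alternatives that leave out the 2 arrays low in Xist, use them as a covariate or fit a block to the CDPs alone were chosen after seeing the data; the rest were planned. Of 6086 recomputed values of named genes 5744 stayed on their side of the threshold, 327 lost the call, 15 gained it and 0 changed direction with a call; of 1122 list tests the numbers were 1042, 61, 19 and 0. Both filters on dim genes, the mean of probe sets, every probe set, both scalings and trended moderation left each total count within 1.5 times its value, though quantile normalization took the genes higher at the first step from 768 to 1216 and those lower at the second from 370 to 654. Array weights gave 6430, 3062 and 6955 genes at the first step, the second step and the whole span, 8701 by the F test and 681 in the same direction at both steps, with weights from 0.15 for replicate 1 of the Zbtb46-pos CDPs to 9.2. Fits of only 2 groups gave 1858 and 850 genes at the steps and 3936 over the whole span. An adjusted p under 0.01 gave 1405, 543, 1877, 2094 and 152, and a fold of at least 2 as well gave 466, 243, 842 and, for both steps, 73, by construction. Without the arrays low in Xist the counts were 4495 and 4066 at the steps, 6203 by the F test and 689 for both steps; as a covariate they gave 5359, 3130, 6197 and 658. With the replicate number as a block the counts were 3460, 1443, 3467, 4285 and 410, with 35 list calls, and 3174 at the first step in the CDPs alone, of which 2391 were shared. Leaving out 1 array at a time gave 1793 to 5268 genes at the first step, 662 to 2672 at the second, 2250 to 4300 over the span, 2624 to 6273 by the F test, 196 to 513 for both steps, 32 to 38 list calls and a position of 0.555 to 0.579. The array with most influence was replicate 1 of the Zbtb46-pos CDPs (5268, 2672 and 6273 without it). Without replicate 1 or 3 of the Zbtb46-neg CDPs the first step gave 1911 or 1793. The second step gave 860 without replicate 2 of the Zbtb46-pos CDPs and 662, 790 and 662 without each pre-CD8 DC array; both steps shared 211 and 228 without replicates 2 and 3 of the Zbtb46-pos CDPs and 207 and 196 without replicates 1 and 3 of the pre-CD8 DCs. The position was 0.604 over all genes, 0.543 over genes with a fold of at least 2 and 0.555 without the arrays low in Xist. With an estimated correlation 10 lists were called, and with fry 38. Quantile normalization added calls of the B cell list at the first step (adjusted p = 0.0144), the mitosis and lysosome lists at the second (0.0206 and 0.00449) and the lysosome list over the span (0.0474). Unless the construction gives it, the cause was not tested. Signal over background limits dim genes: the table holds no background values, so a low signal such as that of Cd8a cannot be told from none.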

Other observations

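The gene families in this and the next paragraph were chosen after seeing the data. So were the tests of array quality, of male mice, of replicate 1 of the Zbtb46-pos CDPs, of neutrophil genes in each array and of simulated mixtures. The other tests were set down before they were run. Those of neutrophil genes over both groups, of the spread of signals and of a mixture still concern patterns or arrays already seen in the data. Among 39 families, each tested in 3 comparisons, mitochondrial ribosomal proteins had 38 of 77 members lower and 1 higher at the first step (median -0.45, camera adjusted p = 6.65e-19, and adjusted p = 0.175 with an estimated correlation). At the second step 12 were higher and 0 lower (median 0.29, camera adjusted p = 1.37e-15, and adjusted p = 0.268 with an estimated correlation). Cytosolic ribosomal proteins had 27 of 67 lower and 1 higher, then 6 higher and 1 lower (medians -0.28 and 0.19, camera adjusted p = 9.06e-12 and 3.22e-09, and adjusted p = 0.235 and 0.321 with an estimated correlation). Proteasome genes had 15 of 40 lower, then 6 higher (medians -0.40 and 0.34, camera adjusted p = 2.27e-09 and 2.61e-09, and adjusted p = 0.283 and 0.321 with an estimated correlation). At the first step 12 of 18 tRNA synthetases were lower (median -0.44, camera adjusted p = 8.67e-08, and adjusted p = 0.128 with an estimated correlation). So were 7 of 10 subunits of the CCT chaperonin, which folds tubulin and actin (median -0.67, camera adjusted p = 0.000145, and adjusted p = 0.233 with an estimated correlation). With all genes in 4 bins by mean signal, the brightest bin moved alike, by medians of -0.14 and then 0.11 (-0.01 at the first step after another quantile normalization). The directions of the families in this paragraph were the same without the 2 arrays low in Xist and after another quantile normalization, but several medians shrank. Those of mitochondrial ribosomal proteins were -0.31 and 0.20 after quantile normalization, those of cytosolic ribosomal proteins -0.19 and 0.09, and those of proteasome genes -0.24 and 0.19 without the 2 arrays.

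Histone genes went the other way, 8 of 31 higher and 1 lower at the first step (median 0.38, camera adjusted p = 5.97e-05, and adjusted p = 0.283 with an estimated correlation). The Slamf family of immune receptors, to which Slamf7 belongs, had 5 of 9 members higher and 1 lower over the whole span (median 0.59, camera adjusted p = 9.74e-05, and adjusted p = 0.0766 with an estimated correlation). Single genes, also picked after their values were seen, turned around between the steps. E2f7 rose by 0.90 and then fell by 0.87, E2f8 rose by 0.60 and fell by 0.65, Esco2, a cohesin acetyltransferase, rose by 0.86 and fell by 0.51, and Rrm2, a ribonucleotide reductase subunit, rose by 0.38 and fell by 0.66. The sialic acid receptor gene Cd33 rose by 0.90 and fell by 1.29. The ATP receptor genes P2rx7 and P2rx4 dipped, falling by 1.56 and 1.10 and then rising by 0.96 and 0.90, and so did the kinase gene Eif2ak2 (-0.81, then 0.89).

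Neutrophil transcripts were higher in replicate 1 of both CDP groups, with a median shift of 3.90 over 6 genes. An overall difference of these arrays in quality stays open: 3 other lineage lists had a largest median shift of 0.07, but only 7 of their 40 members lay above the median gene signal of 6.96, where a shift would show best, and the arrays had the lowest weights (0.35 and 0.15) and more Fos. RNA of maturing neutrophils may be a source: 13 neutrophil genes not looked at before, none in the granulocyte list and 2 above that median in the other 7 arrays, shifted by a median of 0.36, above the 95th percentile of 0.05 of 10000 random lists, though by only 0.09 in the Zbtb46-neg array (95th percentile 0.05) against 0.66 in the Zbtb46-pos array (0.07), with 8 genes higher in both. Yet the shifts were far below those of Ngp, with Retnlg at 0.02 and 0.67 and Ly6g at -0.07 and -0.12, so mature cells are not shown, and a sort on lineage markers would remove them, though the labels give no gates; the eosinophil granule genes Epx (0.33 and 2.17) and Prg2 (0.67 and 2.88), picked after their values were seen, were higher too, so neutrophils need not be the only source. These arrays were low in Xist and high in Y-linked transcripts, as male cells are. Whether male mice account for the neutrophil signal cannot be told apart from the other sources, since no other array is high in Y-linked transcripts. The same 6 genes ranged by 1.45 among pre-CD8 DC arrays that were all high in Xist.

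More genes were lower than higher in Zbtb46-pos than in Zbtb46-neg CDPs, a share of 0.733. Replicate 1 of the Zbtb46-pos CDPs is argued against as the whole cause, since the share was 0.621 without it. A difference in the spread of signals left by the normalization cannot be told apart from a biological one: the interquartile ranges were 2.98, 2.65 and 2.75 in the Zbtb46-neg and 2.75, 2.4 and 2.5 in the Zbtb46-pos CDPs, and another quantile normalization gave a share of 0.564. That scaling removes any real shift of spread as well, which keeps the question open. The falls of the ribosome biogenesis list kept their call under it.

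The Zbtb46-pos CDPs lay between the other populations, as a mixture of these would. A mixture in one proportion allows no gene outside the end values, yet a share of 0.098 of the 3505 genes called at either step lay above or below both ends, 0.081 of 3533 after quantile normalization, 0.259 of 6255 without the 2 arrays low in Xist and 0.197 of 5249 with both changes. Mixtures simulated from the ends, with the residual spread of each gene, gave a share of at most 0.0029 with all arrays, 0.0045 without those 2 and 0.0048 after quantile normalization; a deviation shared by the Zbtb46-pos arrays was not simulated. It also needs the same fraction from rising and falling genes on the linear scale, and these differed by at least 0.33 in each array, with 0.38, 0.23 and 0.26 over 133 rising and 0.70, 0.81 and 0.80 over 82 falling genes (at least 0.32 after quantile normalization and 0.51 without the 2 arrays). A state of their own and a mixture with another population were not tested against each other, and the question of normalization above stays open for the falls.

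Other splits of the arrays were counted for each count of genes. The 10 splits of 6 arrays are too few for a share under 0.05: the real split alone (1) gave 2873, 1319 and 3123 genes, and the highest of the others gave 0, 6 and 0. At the first step, 4 of these splits part all 3 replicate numbers as the real one does, and the others of these gave at most 0. Of 100 splits of the 9 arrays only the real one (1) reached 3816 genes by the F test. The highest other gave 1755 and kept 7 arrays in their own group, while 87 of the others drawn passed no gene. A random grouping of the arrays is thus unlikely to give that count, if the arrays are independent. The labels do not say so, and the splits ignored that arrays of the CDP groups deviated together. The 36 list calls were also reached by the real split alone (1), under the same limit. Yet another split gave 30 list calls, so a wrong grouping of the arrays can come near that count. The number of list calls at the preset correlation therefore says little about the populations. With an estimated correlation 10 lists were called. For the 345 genes with the same direction at both steps (1 split, highest other 0) the count says little, since 95 of the 99 other splits had no gene called at 1 step or both.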
